A study of Mus musculus with 6 samples.

How the data were processed

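RNA from NIH3T3 cells, a line of mouse embryonic fibroblasts, was measured on 6 Affymetrix expression arrays: 3 from cells with wild-type LPAR1 and 3 from cells with mutant LPAR1. LPAR1 is a G protein-coupled receptor for lysophosphatidic acid, a lipid of serum that stimulates growth and cytoskeletal change in fibroblasts. Each genotype had 1 array at 0, 1 at 60 and 1 at 120 minutes, so no combination of genotype and time was repeated. Replicates 1, 2 and 3 of a genotype are its 0, 60 and 120 minute arrays. The labels do not say what was done to the cells at 0 minutes, which mutation the receptor carried, or how many cultures or clones the arrays came from. The deposited values are intensities per probe set, which per the submitters' processing notes were made with Affymetrix Power Tools 1.14.3.1 and PLIER, a method that summarises the probes of a set. The notes do not state the background correction or the scaling between arrays. The values were on a linear scale, and the median intensity of an array lay between 34.1 and 37.3.

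Of 45101 probe sets, 64 were controls, 34958 were paired with 1 gene, 932 with several genes and 9211 with none. The paired sets covered 18194 genes. Gene identifiers of 34754 probe sets matched a RefSeq gene table of assembly GRCm38.p6, which was used only for names and for the order of neighbouring genes. Intensities were used as log2(intensity + 16), without further scaling. Log2 differences and folds are on this scale, which compresses differences at low intensity, so the size of a change with 1 side below the filter level depends on the offset. Each gene was represented by its probe set with the highest mean, and genes below the 40th percentile of mean level (an intensity of 39.2) were left out, which left 10916 genes.

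Genes were tested with limma 3.58.1 in R 4.3.3. The fit had genotype and time as additive terms, empirical Bayes shrinkage with a trend on mean level, and 2 residual degrees of freedom, to which shrinkage added 7.77. The residual holds array noise together with any difference in time course between genotypes. Tests were two-sided, Benjamini-Hochberg adjustment ran over all genes tested within each contrast, and a gene passed at an adjusted p of 0.05. Contrasts were mutant minus wild-type, 60 minus 0 minutes and 120 minus 0 minutes, and both time contrasts share the 0 minute arrays. Time point served as the block that pairs the arrays of the genotypes, taken from the time in the labels. As a check of this pairing, the deviation of each array from the mean of its own genotype was correlated across genes between genotypes. Pearson's r was 0.911 at 0, 0.756 at 60 and 0.871 at 120 minutes, and it was negative for every pair of arrays from different times. Negative values are largely forced by taking deviations from the mean over the 3 times, and positive ones hold the shared time response, so the check bears on time alone and not on a further link between arrays. Genes are not independent replicates in these correlations.

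Genes at least 1.5-fold apart in the same direction at all 3 times were counted without a model and compared with the 3 other ways of swapping genotype within time points. The difference in time course between genotypes had no residual degrees of freedom and was given as values without a test. For it, the median of each gene list was ranked among 10000 random lists of the same size matched on mean level.

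Before the data were examined, 31 gene lists were fixed from textbook knowledge, covering signalling, transcriptional, metabolic and cell-type programmes. A list entered with at least 5 tested members, which 30 lists had. Cartilage and bone markers, with 3 tested members, did not enter. Lists were tested with camera, which compares a list with all other genes, at a preset correlation of 0.01 and with a correlation estimated from the residuals. The second version rests on the 2 residual degrees of freedom and has little power after adjustment. They were also tested with fry, which asks whether the genes of a list move, on balance, in 1 direction. Adjustment ran over the 30 lists within a contrast. Counts of members are given after adjustment over all genes tested and adjusted over the list alone.

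The rule for the genes named was fixed at the same time. For genotype it took Lpar1 and the 12 genes with the largest higher and the 12 with the largest lower difference among those that passed and went the same way at every time point. For each time contrast it took the 8 largest in each direction that went the same way in both genotypes. For the time course it took the 8 genes in each direction with the largest smaller value of the 60 and 120 minute differences. Up to 4 members of each list were named by size of change, those that passed first. Other probe sets of a named gene are stated, above and below the filter level apart, where they had the opposite sign or under 50% of the difference.

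The procedure was tested on simulated data with 50 changed genes per size among 10916. For genotype it recovered 60% at a log2 change of 0.25, 96% at 0.5 and 100% at 1 and at 2. The share recovered at 0.25 and 0.5 was 28% and 94% for 60 minutes and 30% and 88% for 120 minutes. Of the genes called in these simulations, 8.25% for genotype, 7.47% for 60 minutes and 4.79% for 120 minutes had not been changed. In the simulated genotype comparison the 1 list that had been moved was called, as was 1 list that had not. The simulated noise was normal and independent between genes, with the shrunken variances of the fit and no difference in time course between genotypes. Real arrays need not meet this, so the simulated shares can be too favourable.

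Alternatives covered quantile normalization, centring each array on its median, no filter or a 60th percentile filter, the mean of all probe sets of a gene, shrinkage without the trend or with the robust option, offsets of 1 and 64, leaving out each array in turn, leaving the block out, and a 2-fold limit. Further settings chosen after seeing the data were a contrast of 120 minus 60 minutes, scaling, offset and reference time for the time course, and removal of the median change of each run of 50 neighbouring genes. Probe sets without a single gene name were left out of the gene tests and counted separately. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.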

Results

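The data were 6 arrays of NIH3T3 mouse fibroblasts, 3 with wild-type and 3 with mutant LPAR1, taken at 0, 60 and 120 minutes with 1 array per genotype and time. Values are probe-set intensities, and the small number of arrays limits their precision. Mean intensity per array lay between 299 and 308, and log2 levels of genes correlated across genes between arrays of the same time at Pearson's r from 0.989 to 0.990. Arrays of the same genotype at different times correlated at 0.960 to 0.981. The first principal component held 56.3% of the variance and ordered the arrays by time, the second held 20.2% and set the 60 minute arrays apart, and the third held 18.1% and separated the genotypes. The ratio of the 5' to the 3' control probe set of Actb, a sign of RNA integrity and labelling, was 0.579 in wild-type and 0.505 in mutant cells at 0 minutes and lay between 0.650 and 0.699 at the later times. The same ratio for Gapdh lay between 0.954 and 1.03.

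The comparison of genotypes describes how the arrays of mutant cells differed from those of wild-type cells. Since the number of cultures and clones is not stated, its SE and p-values measure no known spread between cultures or clones. They cannot tell an effect of the mutation from a difference in the derivation of the cells. Lpar1 itself, the gene of the manipulated receptor, had a mean intensity of 1305 ± 26.4 (SD, n = 3 arrays) in wild-type and 1483 ± 39.4 (n = 3) in mutant cells. Its log2 difference was 0.18 ± 0.045 (SE; adjusted p = 0.0208), and it was higher in mutant cells at all 3 times. The other Lpar1 probe sets differed by 0.22 and 0.15, and when probe sets rather than genes were fitted, the adjusted p of the 3 sets was 0.0568, 0.109 and 0.158. The Lpar1 call was also lost when either 0 minute array (adjusted p = 0.0558 without the wild-type and 0.0563 without the mutant array) or either 60 minute array (0.102 and 0.103) was left out, and in fits without the shrinkage trend or without the block. Either omission of a time gave the same Lpar1 estimate (log2 0.19 for 0 and 0.16 for 60 minutes), so they are not separate checks. Probe sets for the mouse transcript may not detect an introduced receptor, and the labels do not settle whether a receptor gene was introduced.

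Among genes higher in mutant cells, Afp, which encodes the fetal serum protein alpha-fetoprotein, went from a mean intensity of 11.8 ± 4.44 (SD, n = 3), below the filter level of 39.2, to 126 ± 10.6, which was 3.21 times that level. The size of its log2 difference depended on the offset: 2.36 ± 0.13 at 16 (SE; adjusted p = 3.35e-06), 3.37 at 1 and 1.33 at 64. Ctla2a, which encodes an inhibitor of cysteine proteases, was 3.95-fold higher, from 312 ± 1.06 to 1278 ± 71.7 (log2 1.98 ± 0.055; adjusted p = 5.66e-08). Its neighbouring paralog Ctla2b was higher by log2 1.78 ± 0.060, and probes may not separate such similar genes. The chemokine Ccl2, which attracts monocytes, was higher by log2 1.59 ± 0.080, and the complement protease C1s1 by 1.44 ± 0.072. Aldh1l1, an enzyme of folate metabolism, was higher by log2 1.57 ± 0.097. The other genes named by the rule were AI662270 (2.12), BC023105 (1.99), Dmrtc1a (1.89), Adam22 (1.65), Wscd2 (1.49) and Wdfy4 (1.48). For AI662270, Adam22, Aldh1l1, Wscd2 and Wdfy4 the wild-type mean also lay below the filter level, and offset 64 gave 1.41, 0.94, 0.87, 0.80 and 0.96. Other probe sets, below the filter level, gave 0.11 for Afp (1 of 4), -0.07 for Adam22, 0.09 for Aldh1l1 and -0.15 for Wdfy4. All 12 were higher in the mutant array at each of the 3 times, as the rule required, with adjusted p from 5.66e-08 to 6.97e-05.

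Among genes lower in mutant cells, Phyh, which encodes a peroxisomal enzyme that breaks down phytanic acid, went from an intensity of 306 ± 33.3 (SD, n = 3), 7.80 times the filter level, to 16.8 ± 3.17, below it. Its log2 difference was -3.29 ± 0.083 (SE; adjusted p = 4.59e-08) at offset 16, -4.12 at 1 and -2.19 at 64. Arhgap24 went from 159 ± 16.4, 4.05 times the filter level, to 10.5 ± 1.54, below it (log2 -2.72 ± 0.095; adjusted p = 2.41e-07). Offsets of 1 and 64 gave -3.80 and -1.58, and its other probe set, below the filter level, gave 0.09. The basement membrane gene Nid2 differed by -1.88 ± 0.085, the secreted pentraxin Ptx3 by -1.75 ± 0.072 and the cytochrome P450 gene Cyp3a13 by -1.75 ± 0.063. Akr1c13, an aldo-keto reductase, differed by -1.52 ± 0.080. Glipr1 differed by -1.95 at the probe set used but by 0.01 at its other probe set, so the sets of this gene disagree. The remaining genes named were Cmbl (-1.71), Sorbs2 (-1.64), Dach2 (-1.59), Brinp3 (-1.53) and Tsnax (-1.50). For Glipr1, Nid2, Sorbs2 and Dach2 the mutant mean lay below the filter level, and offset 64 gave -1.32, -1.23, -0.94 and -1.04. Probe sets below the filter level gave -0.27 for Ptx3, -0.63 for Tsnax, and -0.01, -0.10 and 0.14 for Sorbs2. All 12 were lower in the mutant array at each time, as the rule required, with adjusted p from 4.59e-08 to 1.06e-05.

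**Figure D1:**
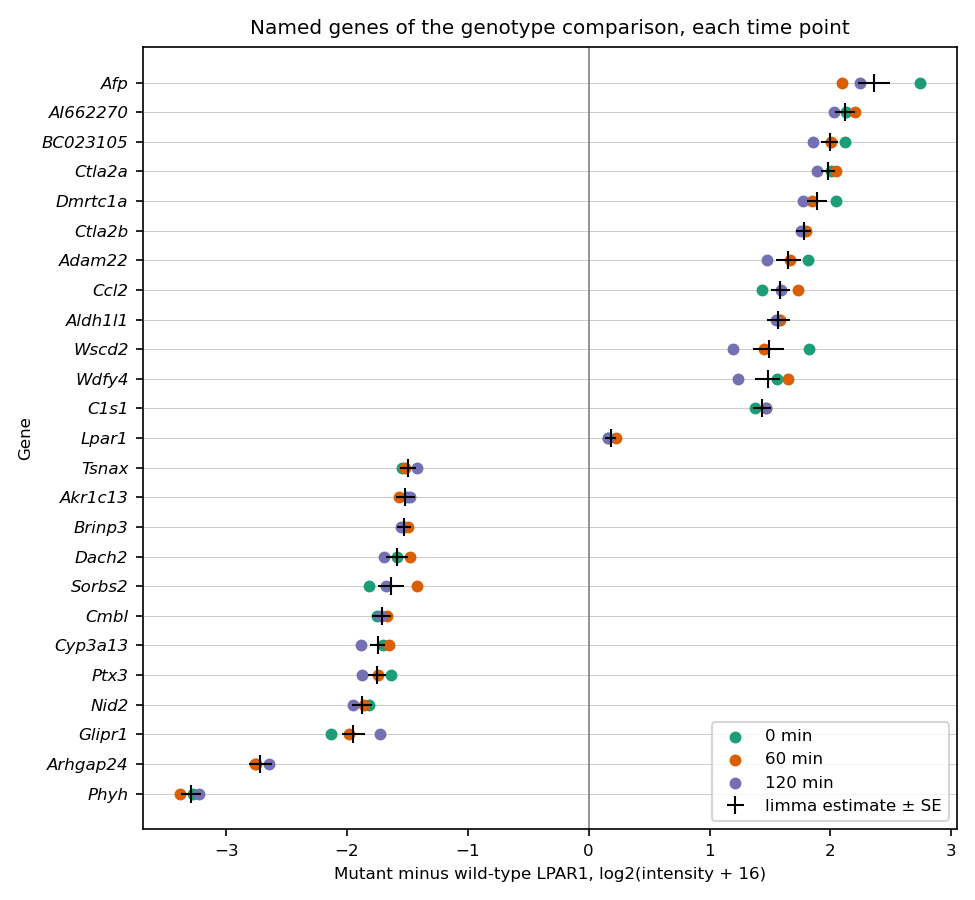
Mutant minus wild-type difference in log2(intensity + 16) (x axis) of each gene named for the genotype comparison (y axis), with a point per time and a cross for the limma estimate with its SE. Phyh lay at -3.29 and Afp at 2.36, sizes that depend on the offset, and Lpar1 at 0.18.

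Of 10916 genes tested, 2112 passed, 1138 higher and 974 lower in mutant cells, with a median absolute log2 difference of 0.28. At least 1.5-fold differences were seen for 74 of the higher and 113 of the lower genes, and at least 2-fold differences for 26 and 32. Without a model, 122 genes were at least 1.5-fold apart in the same direction at all 3 times, 48 higher and 74 lower, against 0 in each of the 3 other swaps of genotype within time points. A 2-fold limit gave 20 higher and 24 lower, and a 60th percentile filter left 45 in either direction at 1.5-fold. With time point left out as the block that pairs the arrays, 89 genes passed, and Ccl2 and Lpar1 were among those that did not. The count was 1397 without the trend in shrinkage, 1394 or 1387 without the wild-type or mutant array of 0 minutes, and 1377 or 1372 without that of 60 minutes. Leaving out either array of a time removes the same pair from the genotype estimate, so the omissions of a time are not separate checks. Lower genes outnumbered higher ones in the counts without either 60 minute array, without the block, and with the mean of all probe sets of a gene (725 higher and 848 lower).

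Genes of the extracellular matrix, the scaffold that fibroblasts secrete, were more often lower than higher in mutant cells. Of 25 tested members 13 were lower and 2 higher, or 15 and 2 adjusted over the list alone (camera adjusted p = 4.74e-06, and adjusted p = 0.527 with an estimated correlation). The collagen genes Col11a1 (log2 -0.55 ± 0.056), Col4a2 (-0.54 ± 0.045) and Col1a1 (-0.49 ± 0.050) and the protease inhibitor Timp1 (-0.51 ± 0.078) were among them. Of 21 focal adhesion and integrin genes, which couple cells to that scaffold, 10 were lower and 1 higher, or 10 and 3 adjusted over the list alone (adjusted p = 0.000452; adjusted p = 0.527 with an estimated correlation). Tenascin C, Tnc, differed by -0.79 ± 0.086, the matrix glycoprotein Thbs1 by -0.59 ± 0.050 and the integrins Itgb3 and Itga1 by -0.50 ± 0.13 and -0.50 ± 0.12 (Itga1 -0.27 at offset 64). Of 22 genes of the unfolded protein response and amino acid stress, 14 were lower and 1 higher, and the same adjusted over the list alone (adjusted p = 9.73e-07; adjusted p = 0.527 with an estimated correlation). Examples were Cth, an enzyme of cysteine synthesis (-0.83 ± 0.081), the amino acid transporter Slc7a5 (-0.58 ± 0.051) and Herpud1, which acts in degradation of endoplasmic reticulum proteins (-0.47 ± 0.056). Fry passed none of the lists in this paragraph (fry adjusted p = 0.0898 for each).

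Immediate early transcription factors, which growth stimuli induce within minutes, were lower for 11 and higher for 1 of 30 members, with the same counts adjusted over the list alone (adjusted p = 0.00104; adjusted p = 0.527 with an estimated correlation). Fos differed by -0.62 ± 0.13, Nr4a3 by -0.43 ± 0.11, Klf2 by -0.41 ± 0.057 and Ier2 by -0.38 ± 0.065. For Fos the difference was -0.088 at 0, -0.75 at 60 and -1.01 at 120 minutes. For Nr4a3 it was -0.088, -0.49 and -0.70, with both 0 minute arrays below the filter level. Of the 30 members 18 were lower at 0, 23 at 60 and 26 at 120 minutes, so the estimates average over unlike time points. Of 11 Wnt and Notch targets, 4 were lower, and 4 adjusted over the list alone (adjusted p = 0.00708; adjusted p = 0.527 with an estimated correlation). These were the Notch target Hes1 (-1.20 ± 0.16), the Notch ligand Jag1 (-0.53 ± 0.057), and Ccn5 (-1.19 ± 0.10) and Ccn4 (-0.31 ± 0.065), secreted proteins that Wnt signalling induces. Hes1 and Ccn5 had a mutant mean below the filter level, and offset 64 gave -0.72 and -0.65. Of 6 tested neural and glial markers, 4 were lower, and 4 adjusted over the list alone (adjusted p = 0.00708; adjusted p = 0.527 with an estimated correlation): the calcium-binding protein S100b (-0.80 ± 0.068), the tubulin Tubb3 (-0.46 ± 0.10, or -0.30 at offset 64), the adhesion molecule Ncam1 (-0.43 ± 0.091) and the intermediate filament gene Nes (-0.29 ± 0.088). Of 15 circadian clock genes, 3 were lower, or 5 adjusted over the list alone (adjusted p = 0.0144; adjusted p = 0.565 with an estimated correlation), among them Rora (-0.47 ± 0.073) and Bhlhe40 (-0.31 ± 0.059). G2/M and mitotic genes were the list higher in mutant cells: 5 of 27 were higher, and 5 adjusted over the list alone (adjusted p = 0.00447; adjusted p = 0.527 with an estimated correlation). The mitotic motor genes Kif11 (0.36 ± 0.075) and Kif23 (0.29 ± 0.067), the cyclin gene Ccna2 (0.28 ± 0.057) and Cdk1 (0.27 ± 0.048) were among them.

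Lists that did not pass for genotype, 22 of 30, had camera adjusted p from 0.0529 to 0.973. Among 14 genes of lysophosphatidic acid receptors and metabolism, 2 were higher and 4 lower, and the same adjusted over the list alone, the largest being the lipid phosphatase Plpp3 (log2 -1.48 ± 0.11). Of 15 tested inflammatory and NF-kB target genes, 4 were higher and 3 lower, and the same adjusted over the list alone. Ccl7, a chemokine gene related to Ccl2, was higher by 1.35 ± 0.087 and the cytokine gene Il11 differed by -0.73 ± 0.19. Of 22 FoxO targets and quiescence-linked genes, 9 were higher and 2 lower, or 10 and 3 adjusted over the list alone, led by Pdk4, a kinase that inhibits pyruvate dehydrogenase (1.34 ± 0.073). Of 23 SRF and MRTF target cytoskeletal genes, 5 were higher and 4 lower, and the same adjusted over the list alone, with Tagln, an actin-binding protein, at -1.31 ± 0.18 (-2.05 at offset 1 and -0.87 at offset 64) and Mylk, a myosin kinase, at 0.78 ± 0.087. For p53 targets the mean and median difference were positive and the direction of the test negative. For heat shock genes the mean was negative against a positive median and test, and for MYC targets the mean was positive against a negative median and test. Fry passed 4 lists for genotype, 2 of them also called by camera: G2/M genes (fry adjusted p = 0.0390) and Wnt and Notch targets (0.0338). The other 2, not called by camera, were FoxO targets, on balance higher, and adipocyte markers, on balance lower (fry adjusted p = 0.0338 for each). Camera calls that fry did not pass included neural markers (fry adjusted p = 0.0573), circadian genes (0.0898) and immediate early factors (0.200). Leaving out the block ended the camera calls of immediate early (adjusted p = 0.387), G2/M (0.239) and circadian genes (0.472). The G2/M call was also lost without the wild-type or mutant array of 120 minutes (0.050001 and 0.0504), and the circadian call without that of 0 minutes (0.0727 and 0.0722).

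The comparison of 60 with 0 minutes describes what changed in both genotypes over the first hour. Egr3, an immediate early transcription factor, rose 48.7-fold (log2 5.61 ± 0.085, SE; n = 2 arrays per time; adjusted p = 7.69e-11), though a weaker probe set of the gene gave -0.22. Dusp5, a phosphatase that inactivates ERK, rose by log2 5.09 ± 0.11. Hbegf and Ereg, which encode ligands of the EGF receptor, rose by 4.84 ± 0.11 and 4.46 ± 0.16. Thbs1 rose by 4.67 ± 0.061, the transcription factors Egr2 and Fosb by 4.66 ± 0.088 and 4.58 ± 0.16, and the rhythmically expressed gene Noct by 4.47 ± 0.081. Txnip, which binds thioredoxin and limits glucose uptake, fell 10.9-fold (log2 -3.44 ± 0.082; adjusted p = 1.73e-09). Pik3ip1, an inhibitor of PI3 kinase, changed by log2 -2.22 ± 0.11, the pro-apoptotic gene Bmf by -1.67 ± 0.14, the phosphodiesterase gene Pde4b by -1.50 ± 0.094 and the cyclin gene Ccng2 by -1.47 ± 0.10. Rgs2, a regulator of G protein signalling, changed by -1.60 ± 0.11, with 1 of its 3 other probe sets at -0.30. H3f3a (-1.63 ± 0.13) and Clec2d (-1.58 ± 0.13) fell at dim probe sets, the former with a mean intensity of 62.7 in wild-type cells. Dusp5 and Fosb at 0 minutes and H3f3a and Clec2d at 60 minutes had means below the filter level, and offset 64 gave 4.02, 3.59, -1.0 and -1.04. Probe sets below that level gave -0.21 and 0.13 for Bmf and 0.11, -0.16 and -0.04 for Pde4b. All 16 genes went the same way in both genotypes, as the rule required.

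Of 30 immediate early transcription factors 28 rose and 1 fell, and the same adjusted over the list alone (camera adjusted p = 4.09e-51; adjusted p = 0.353 with an estimated correlation), with Egr3, Egr2 and Fosb at their head. Of 15 feedback regulators of the ERK pathway 11 rose, or 12 adjusted over the list alone (adjusted p = 1.53e-21; adjusted p = 0.353 with an estimated correlation). Errfi1, an inhibitor of the EGF receptor, rose by 4.26 ± 0.084, Phlda1 by 3.02 ± 0.060 and the ERK phosphatase Dusp6 by 2.40 ± 0.11. SRF and MRTF target cytoskeletal genes rose for 20 of 23 members, or 21 adjusted over the list alone (adjusted p = 1.66e-27; adjusted p = 0.353 with an estimated correlation). Tagln rose by 3.58 ± 0.22, the actin genes Acta2 and Actg2 by 3.25 ± 0.047 and 1.95 ± 0.12 (Actg2 1.1 at offset 64), and Srf by 2.39 ± 0.077. The 5' to 3' ratio of Actb, whose gene is in that list, was 0.579 and 0.505 at 0 minutes against 0.650 to 0.699 at the later times. Of 22 YAP and TEAD targets 9 rose, or 10 with 1 lower adjusted over the list alone (adjusted p = 1.52e-08; adjusted p = 0.353 with an estimated correlation), among them the matricellular genes Ccn2 (3.54 ± 0.055) and Ccn1 (2.52 ± 0.11) and the cofactor gene Ankrd1 (2.86 ± 0.083).

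Of 15 inflammatory and NF-kB target genes 9 rose, with 9 higher and 1 lower adjusted over the list alone (adjusted p = 1.20e-06; adjusted p = 0.354 with an estimated correlation), including the prostaglandin synthase Ptgs2 (log2 2.64 ± 0.076) and the chemokine Cxcl1 (1.75 ± 0.11). Growth factors and their receptors rose for 7 and fell for 1 of 18 members, and the same adjusted over the list alone (adjusted p = 0.000481; adjusted p = 0.421 with an estimated correlation), with the activin subunit Inhba at 1.88 ± 0.12. Of 17 TGF-beta targets 6 rose and 2 fell, or 6 and 3 adjusted over the list alone (adjusted p = 0.000573; adjusted p = 0.362 with an estimated correlation), with the inhibitory gene Smad7 at 1.94 ± 0.10. Of 21 focal adhesion genes 7 rose and 1 fell, or 8 and 1 adjusted over the list alone (adjusted p = 0.000289; adjusted p = 0.378 with an estimated correlation), and the adaptor Bcar1 rose by 0.94 ± 0.060.

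Circadian clock genes rose for 7 and fell for 2 of 15 members, or 7 and 3 adjusted over the list alone (adjusted p = 0.000213; adjusted p = 0.378 with an estimated correlation), with Nfil3 at log2 2.49 ± 0.090, Per2 at 2.04 ± 0.089 and Per1 at 1.66 ± 0.077. Heat shock genes rose for 3 and fell for 1 of 15, and the same adjusted over the list alone (adjusted p = 0.00127; adjusted p = 0.378 with an estimated correlation), led by the chaperone gene Dnajb4 (1.32 ± 0.052). Of 19 p53 targets 6 rose and 3 fell, and the same adjusted over the list alone (adjusted p = 0.0144; adjusted p = 0.475 with an estimated correlation), with the growth-inhibiting gene Btg2 at 3.22 ± 0.070 and Sesn1, a stress-induced inhibitor of mTOR, at -0.77 ± 0.084. Of 22 genes of the unfolded protein response and amino acid stress 6 rose and 3 fell, or 8 and 4 adjusted over the list alone (adjusted p = 0.0151; adjusted p = 0.6075 with an estimated correlation). Chac1, which degrades glutathione, rose by 1.67 ± 0.056, and Ddit4, an inhibitor of mTOR, changed by -1.43 ± 0.14. Of 5 tested skeletal muscle markers 3 rose, and 3 adjusted over the list alone (adjusted p = 0.00135; adjusted p = 0.354 with an estimated correlation). These were the striated muscle actin genes Acta1 (1.64 ± 0.17) and Actc1 (1.46 ± 0.12), which SRF also induces, and the transcription factor Mef2c (0.69 ± 0.076).

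In total 1970 genes passed at 60 minutes, 801 higher and 1169 lower, and of these 331 and 184 changed at least 1.5-fold and 150 and 39 at least 2-fold. Of the 14 lists that passed camera, 1 is not described here. The other 16 lists did not pass, with adjusted p from 0.0518 to 0.970, and fry passed 11 lists, 9 of them called by camera. FoxO targets and quiescence-linked genes passed fry (fry adjusted p = 0.0111) but not camera (camera adjusted p = 0.0518), with 5 of 22 higher and 9 lower, or 5 and 10 adjusted over the list alone. Mean, median and test direction differed in sign for matrix proteases, lysophosphatidic acid receptors and metabolism, Wnt and Notch targets, and neural and glial markers, each with a negative median. For cholesterol biosynthesis, DNA replication, hypoxia and glycolysis, and macrophage and leukocyte markers, mean and median were negative and the test direction positive. Centring each array on its median turned the split to 1012 higher and 619 lower, 590 genes passed without genotype as a block, and 1184, 1163 and 1156 passed without the wild-type 0 minute, mutant 0 minute and mutant 60 minute array, with more higher than lower genes without the block and without either 0 minute array. Without the wild-type 60 minute array the split was 753 higher and 719 lower. The unfolded protein response call was lost under quantile normalization (adjusted p = 0.0510), without the block (0.0725) and without the mutant 60 minute array (0.0934).

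At 120 against 0 minutes, Thbs1 was 27.6-fold higher (log2 4.79 ± 0.061, SE; n = 2 arrays per time; adjusted p = 5.41e-11). The transcription factor Fosl1 rose by 4.72 ± 0.088, the nuclear receptor Nr4a3 by 4.50 ± 0.13 and Tagln by 4.05 ± 0.22. Hbegf (4.44 ± 0.11), Ereg (3.99 ± 0.16), Dusp5 (4.01 ± 0.11) and Egr3 (4.04 ± 0.085) were also among the 8 largest rises, with the weaker Egr3 probe set at -0.08. Txnip was again the largest fall, at log2 -3.36 ± 0.082 (adjusted p = 3.88e-09), followed by Bmf (-3.17 ± 0.14), Ccng2 (-2.99 ± 0.10) and Pik3ip1 (-2.93 ± 0.11). Ddit4 changed by -2.75 ± 0.14, the p53-induced gene Trp53inp1 by -2.62 ± 0.070 and Id3, an inhibitor of transcription factors of differentiation, by -2.50 ± 0.12. Fos, which had risen by 1.63 at 60 minutes, lay 5.87-fold below its starting level (-2.55 ± 0.17). Fosl1, Nr4a3, Tagln and Dusp5 had means below the filter level at 0 minutes, and offset 64 gave 3.80, 2.98, 2.88 and 2.99. Probe sets below that level gave 0.01 and 0.01 for Nr4a3, -0.38 and 0.16 for Bmf and -0.13 for Trp53inp1. All 16 genes went the same way in both genotypes, as the rule required.

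Genes linked to quiescence fell as a group: of 22 FoxO targets and quiescence-linked genes 19 fell and 1 rose, and the same adjusted over the list alone (camera adjusted p = 2.08e-08; adjusted p = 0.339 with an estimated correlation). Besides Txnip, Ccng2 and Pik3ip1, the ubiquitin ligase gene Fbxo32 changed by log2 -2.48 ± 0.11 (-1.56 at offset 64). Of 27 G2/M and mitotic genes 25 fell, or 26 adjusted over the list alone (adjusted p = 2.68e-08; adjusted p = 0.339 with an estimated correlation). Bub1b, of the spindle checkpoint, changed by -0.94 ± 0.11, and the mitotic genes Kif20a, Cenpe and Plk1 by -0.91 ± 0.076, -0.86 ± 0.12 and -0.84 ± 0.097. MYC targets and ribosome biogenesis genes rose for 15 of 26 members, or 18 with 1 lower adjusted over the list alone (adjusted p = 5.45e-09; adjusted p = 0.397 with an estimated correlation). Odc1, the enzyme that starts polyamine synthesis, rose by 1.20 ± 0.11 and the nucleolar genes Nop56 and Nop58 by 1.08 ± 0.071 and 0.98 ± 0.083.

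SRF and MRTF targets rose for 20 and fell for 1 of 23, or 21 and 1 adjusted over the list alone (adjusted p = 1.05e-14; adjusted p = 0.397 with an estimated correlation), with Acta2 at log2 3.32 ± 0.047. ERK feedback regulators rose for 11 and fell for 1 of 15, and the same adjusted over the list alone (adjusted p = 5.45e-09; adjusted p = 0.397 with an estimated correlation), with Errfi1 at 3.39 ± 0.084 and Dusp4 at 3.32 ± 0.090. Immediate early transcription factors rose for 17 and fell for 6 of 30, or 17 and 7 adjusted over the list alone (adjusted p = 2.16e-06; adjusted p = 0.397 with an estimated correlation), with Nr4a1 at 3.14 ± 0.050. Focal adhesion genes rose for 13 of 21, or 13 with 1 lower adjusted over the list alone (adjusted p = 5.78e-06; adjusted p = 0.401 with an estimated correlation), with Tnc at 1.13 ± 0.11. YAP and TEAD targets rose for 13 and fell for 2 of 22, and the same adjusted over the list alone (adjusted p = 0.000104; adjusted p = 0.397 with an estimated correlation), with Ccn2 at 2.41 ± 0.055 and the kinase gene Nuak2 at 1.72 ± 0.068.

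Extracellular matrix genes, which had 3 of 25 members higher and 1 lower at 60 minutes, had 8 higher and 1 lower at 120 minutes, and the same adjusted over the list alone at each time (adjusted p = 0.000737 at 120 minutes; adjusted p = 0.483 with an estimated correlation). The inhibitor of calcification Mgp rose by log2 2.39 ± 0.13 and the protease inhibitors Timp1 and Timp3 by 1.84 ± 0.096 and 1.05 ± 0.052. Growth factors and receptors rose for 8 and fell for 4 of 18, or 9 and 4 adjusted over the list alone (adjusted p = 0.00127; adjusted p = 0.483 with an estimated correlation), with Pdgfa at 1.83 ± 0.068. Heat shock genes rose for 7 and fell for 1 of 15, and the same adjusted over the list alone (adjusted p = 0.00184; adjusted p = 0.470 with an estimated correlation), with Dnajb4 at 1.17 ± 0.052. Inflammatory and NF-kB target genes rose for 8 and fell for 3 of 15, and the same adjusted over the list alone (adjusted p = 0.00654; adjusted p = 0.460 with an estimated correlation), with Il11 at 2.30 ± 0.23 (1.49 at offset 64) and the growth factor Csf1 at 1.55 ± 0.080. Skeletal muscle markers rose for 3 of 5, or 4 with 1 lower adjusted over the list alone (adjusted p = 0.00312; adjusted p = 0.397 with an estimated correlation), again Acta1 (2.14 ± 0.17), Actc1 (1.63 ± 0.12) and Mef2c (1.30 ± 0.076).

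At 120 minutes 5129 of 10916 genes passed, 1768 higher and 3361 lower. At least 1.5-fold changes numbered 575 and 868, and at least 2-fold changes 228 and 188. Camera adjusted p of the 17 lists that did not pass ran from 0.0918 to 0.911, and fry passed 22 lists, among them all 13 called by camera. Among the lists camera did not call, matrix proteases, lysophosphatidic acid receptors and metabolism, circadian genes, Wnt and Notch targets, and macrophage markers had a positive mean and test direction with a negative median. Adipocyte markers had a positive mean with a negative median and test, and neural markers a negative mean and median with a positive test. Without genotype as a block 2772 genes passed, 1040 higher and 1732 lower.

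**Figure D2:**
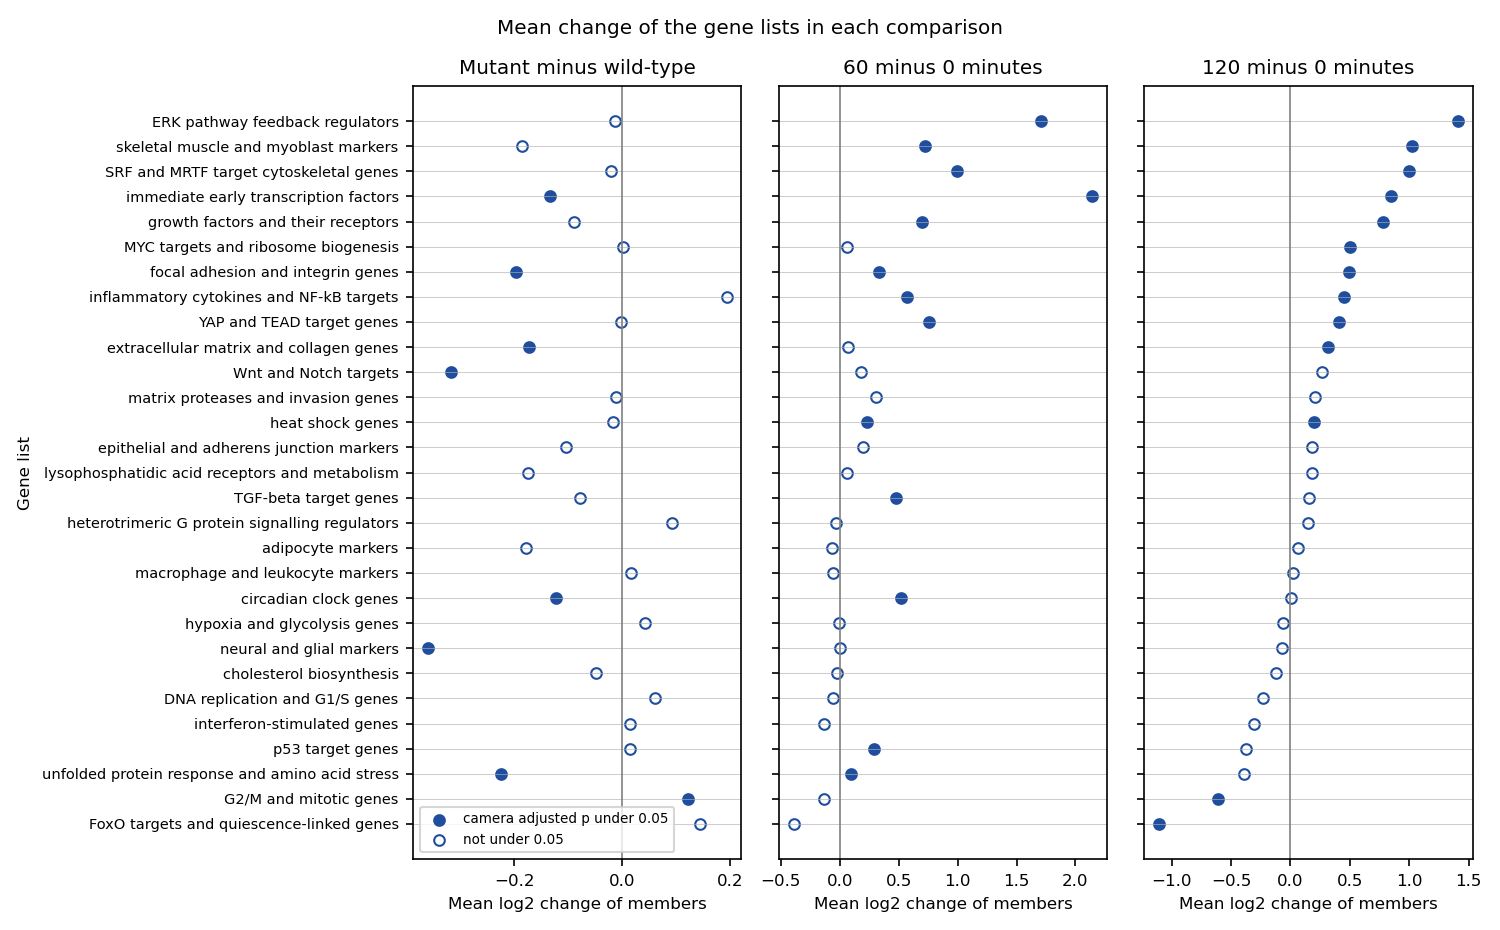
Mean log2 difference of the tested gene lists, 1 list left out (x axis), for mutant against wild-type, 60 against 0 and 120 against 0 minutes, with filled points for lists that passed camera at the preset correlation of 0.01 and open points for the rest. At 120 minutes FoxO targets lay at -1.10 and G2/M genes at -0.61, and immediate early transcription factors moved from 2.14 at 60 minutes to 0.85.

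The design also asks whether the time course differed between genotypes, which was given as values without a test since each genotype and time had 1 array. Changes from 0 minutes correlated across genes between genotypes at Pearson's r = 0.860 at 60 and 0.911 at 120 minutes, where genes are not independent replicates. Of 150 genes that rose at least 2-fold at 60 minutes, 82 had the larger rise in mutant cells. At 120 minutes this was so for 56 of 228 genes, with a median rise of log2 1.51 in wild-type and 1.35 in mutant cells. Of the genes that fell at least 2-fold, the fall was larger in mutant cells for 22 of 39 at 60 and 112 of 188 at 120 minutes.

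Sctr, the secretin receptor gene, had a change from 0 minutes that was higher in mutant than in wild-type cells by log2 1.59 at 60 and 1.34 at 120 minutes, from an intensity of 16.3 at 0 minutes in mutant and 73.6 in wild-type cells. Offset 64 gave 0.85 and 0.70. Tagln started at an intensity of 2.21 in mutant and 58.2 in wild-type cells, and its difference in response had no stable size or direction: 1.21 and 0.95 at offset 16, 3.36 and 3.11 at offset 1, and 0.15 and -0.11 at offset 64. The other genes with higher values in mutant cells were Lncpint (0.75 at 60 minutes), Cdk5r1 (0.73, with 0.13 at its other bright probe set), Tubb2a-ps2 (0.57), Lama3 (0.53), Paqr7 (0.53) and Abraxas1 (0.52). For the last 4 of these offset 64 gave 0.32, 0.31, 0.35 and 0.31. Slc44a4, of a family of choline transporter-like proteins, had a lower value in mutant cells by -2.93 and -2.06, starting at 231 in mutant and 16.1 in wild-type cells, and offset 64 gave -1.87 and -1.23. Arc, an immediate early gene, rose in both genotypes, by 4.34 in wild-type and 3.60 in mutant cells at 60 minutes. The others with lower values were the mechanosensitive channel gene Piezo2 (-1.07 at 60 minutes), Ccdc38 (-1.04), Agbl5 (-0.94), Slc22a12 (-0.94), the epithelial adhesion gene Epcam (-0.72) and Akr1c12 (-0.71). Offset 64 gave -0.65 for Piezo2, -0.67 for Ccdc38, -0.61 for Agbl5 and -0.31 for Akr1c12. In all, 11 of the 16 values at 60 minutes were smaller by over 1.5 times at offset 64, and 11 of the 16 genes had an array below the filter level. Probe sets below that level gave a 60 minute difference of the opposite sign for Tubb2a-ps2 (-0.28), Cdk5r1 (-0.11), Paqr7 (-0.01), Agbl5 (0.19 and 0.18), Slc22a12 (0.33) and Piezo2 (0.25). Others gave a smaller one for Lama3 (0.15), Epcam (-0.18) and a further set of Tubb2a-ps2 (0.08).

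**Figure D3:**
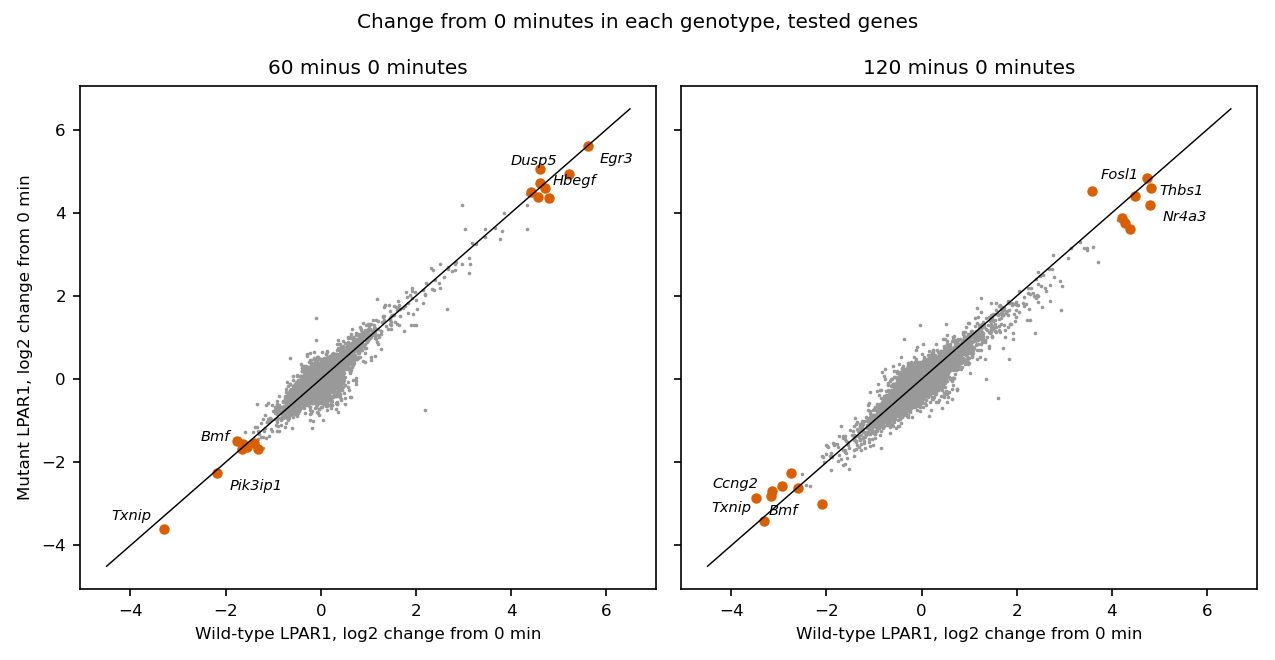
Log2 change from 0 minutes in wild-type (x axis) and mutant cells (y axis) for each tested gene at 60 and 120 minutes, with the genes named for each time in colour, the 3 largest per direction labelled, and a line of equal change. Pearson's r across genes was 0.860 at 60 and 0.911 at 120 minutes.

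For immediate early transcription factors, the median difference in response was log2 -0.13 at 60 and -0.12 at 120 minutes, at percentiles 0 and 0.35 of 10000 random lists of like expression. ERK feedback regulators lay at -0.06 and -0.23 (percentiles 1.35 and 0.01), with a smaller rise or larger fall in mutant cells for 13 of 15 members at 120 minutes. Growth factors and their receptors (-0.18, percentile 0.12) and heterotrimeric G protein signalling regulators (-0.17, percentile 0.06) had low medians at 120 minutes. MYC targets lay high at both times (0.10 and 0.05, percentiles 98.6 and 99.6), as did TGF-beta targets at 60 minutes (0.13, percentile 99.7) and G2/M genes at 120 minutes (0.08, percentile 99.7). These percentiles treat genes as independent and are not a test across arrays. Random lists were matched on mean level and not on the size of the response, which can place strongly responding lists at the extremes. The median change of immediate early factors at 120 minutes was 0.48 in wild-type and 0.56 in mutant cells. Differences of at least 1.5-fold in the same direction at both times were found for 27 genes, 3 higher and 24 lower in mutant cells, against a mean of 12.9 and at most 22 in 100 sets of arrays simulated without a difference. The count depended on the offset, with 48 genes at offset 1 and 6 (1 higher and 5 lower) at offset 64, where no simulation was run. The simulated noise was normal, with the shrunken variances of the additive fit. Genes of larger variance and faults of a single array were not represented, so 27 genes are not shown to exceed noise. Taken from 60 minutes the counts were 52 higher and 3 lower, and from 120 minutes 29 and 28. A changed reference counts other genes, those whose genotype difference at that time stands apart from both other times. By arithmetic, a gene lower when taken from 0 minutes cannot be lower from 60 or 120 minutes. The counts therefore do not show which arrays the direction rested on.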

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

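Of the tests in this part, the check for compressed values, the levels of rising genes at 120 minutes, the count of calls after removal of neighbouring medians, and the comparisons of the time course under other scalings were chosen only after the results were seen.

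Probe sets without a single gene name were not used in the gene tests. Of 2794 such sets above the filter level, 14 were at least 1.5-fold higher and 8 at least 1.5-fold lower in mutant cells at all 3 times, against 0 for the 3 other swaps of genotype within time points.

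For 12 of 63 named genes the change from 0 minutes went 1 way in wild-type cells at both later times and the opposite way in mutant cells. With 1 array per genotype and time, none of these differences was tested, and 10 of the genes were named because their time courses differed. As the change from 0 to 60 minutes in mutant minus that in wild-type cells, on the log2 scale, they were Sctr 1.59, Tubb2a-ps2 0.57, Lama3 0.53, Slc44a4 -2.93, Agbl5 -0.94, Slc22a12 -0.94, Piezo2 -1.07, Ccdc38 -1.04, Epcam -0.72 and Akr1c12 -0.71. Afp (-0.64) and Wscd2 (-0.37), named for the genotype difference, were the others. The sizes depend on the offset, and at 64 Sctr lay at 0.85 and Slc44a4 at -1.87.

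Many genes differed between genotypes: 2112 passed, and the highest count among the other splits of the 6 arrays into 3 and 3 was 0, so 1 of 10 splits gave as many, and 10 splits are too few for a share under 0.05. Scaling of the arrays is argued against as the whole cause, since at least 90.9% of the calls stayed called in the same direction under quantile normalization and median centring. Part of the differences was shared by neighbouring genes: medians over 207 runs of 50 neighbouring tested genes spread 2.92 times as widely as after shuffling gene order, against 1.31 times for 60 and 1.12 times for 120 minutes (permutation p = 0.000999 for genotype, the smallest that 1000 shuffles can give). With the median of each run removed, 1411 genes passed and 1221 of the 2112 calls (57.8%) remained. Of the 122 genes at least 1.5-fold apart at every time 110 remained (90.2%). The run medians, from log2 -0.21 to 0.21, were too small to make a 1.5-fold difference, so most of these genes had to remain. Shifts of whole runs thus do not account for most of those larger differences, but shifts shared by fewer neighbours were not measured. The small shared shifts are consistent with a difference in copy number between separately grown or selected cells, which was not tested, and the mutation itself, the derivation of the cells, single-gene differences between clones and GC content (no genome sequence was used here) all stay open.

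More genes fell than rose at 120 minutes, 3361 against 1768. Array scaling as the whole cause was predicted to bring the higher share to between 45 and 55%. It reached at most 42.8% under quantile normalization and median centring. Median centring did narrow the split, to 1970 higher and 2631 lower, so scaling stays open as part of the cause. What was done to the cells, which the labels do not state, and the variation of single arrays stay open.

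Rises at 120 minutes were smaller in mutant cells: of 228 genes with at least a 2-fold rise, 56 rose more there. Array scaling is argued against by the share of genes with the larger rise in mutant cells, at most 28.5% under quantile normalization and median centring. The falls go against compression of all values on the mutant array of 120 minutes. Without further scaling, these were smaller there for 40.4% of 188 genes. The falls were not counted under other scalings, and a lower scale of that array could hide compression, which therefore stays open. Falling genes cannot test a compression of bright values alone, which also stays open. Values that go against a higher starting level in mutant cells were a median difference of log2 -0.0142 at 0 minutes, or -8.70% of the median shortfall of 0.16, and of -0.15 at 120 minutes, where 173 of the 228 genes were lower. It still stays open, since the genes went both ways at 0 minutes (113 higher, quartiles -0.20 and 0.17), and the upper quartile at 120 minutes was -0.00163 as scaled but 0.02 under quantile normalization and 0.03 under median centring. A difference in culture, harvest or handling of that single array and an altered response of the mutant receptor were not tested and stay open.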

How the results depend on the processing

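Settings for the time course and the removal of neighbouring medians were chosen after the data were seen; all others were planned. Among genotype counts (2112 as reported), 1397 genes passed without the shrinkage trend and 89 without the block; the other planned settings with all arrays gave 1573 to 2500, and leaving out 1 array gave 1372 to 2156. For 60 minutes (1970), 590 passed without the block, 1504 to 2263 otherwise, and 1156 to 2510 with 1 array left out. For 120 minutes (5129), 2772 passed without the block, 3952 to 5234 otherwise, and 3686 to 5318 with 1 array left out. Those fits had 1 residual degree of freedom and assumed a lone array to vary like the rest. For genotype, leaving out either array of a time removes the same pair from the estimate, so the omissions of a time are not separate checks. Leaving out the block puts the differences between times, or between genotypes, into the residual, and a 60th percentile filter tests fewer genes; for the other changes the cause was not tested. Genes at least 1.5-fold apart at every time (122) numbered 45 with the 60th percentile filter, 44 at 2-fold, and 91 to 156 otherwise. Time-course differences (27) numbered 48 at offset 1 and 6 at offset 64. The counts of 55 and 57 when taken from 60 and 120 minutes answer another question and are not alternatives to the 27. The Lpar1 difference (log2 0.18) ranged from 0.16 to 0.20 with 1 array left out, and its probe sets, fitted among all sets, gave 0.18, 0.22 and 0.15 without passing. With an estimated correlation 0 lists passed in each contrast, in place of 8, 14 and 13. That version rests on the 2 residual degrees of freedom. Lists whose estimated correlation lay below the preset 0.01, such as G2/M genes (-0.0132) and FoxO targets (-0.0194), lost their 120 minute calls too. The loss of every call therefore does not tell the lists apart. No gene named for genotype or for 60 or 120 minutes, and no list, reversed under any setting run; besides Lpar1, Ccl2 lost its call without the block. Of the values of the 16 time-course genes at 60 minutes 71 kept their size and 23 moved, mostly with the offset, and Tagln at 120 minutes turned from 0.95 to -0.11 at offset 64. Over all lists and settings, 816 list results kept their side of the threshold, 45 lost and 39 gained a call. Low signal over background limits the test of a gene: 17 of 25 named genotype genes, Afp and Phyh among them, fell below the 60th percentile filter.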

Other observations

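The contrast of 120 with 60 minutes in this part was added only after the data were seen.

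Many early rises were smaller at 120 than at 60 minutes. In the same limma fit, 2744 genes differed between 120 and 60 minutes, 1112 higher and 1632 lower. Of the 150 genes that rose at least 2-fold by 60 minutes, 84 were lower again at 120 minutes, 26 were higher still, and 10 lay below their starting level. The largest drops from 60 to 120 minutes were in Fos (log2 -4.18), Egr2 (-2.90), Fosb (-2.74) and Junb (-2.41), immediate early transcription factors, in Bcl6 (-2.71), a transcriptional repressor, and in Filip1l (-2.70). Btg2 (-2.44), the vasodilator peptide gene Adm (-2.43), the clotting initiator F3 (-2.34) and the stress-induced factor Atf3 (-2.16) followed. Bcl6, Filip1l and Adm had risen by 0.84, 0.84 and 0.64 at 60 minutes and lay below their 0 minute level by 120 minutes (-1.88, -1.86 and -1.80).

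Other genes rose mainly in the second hour. Hivep3, a zinc finger gene, was 2.69 higher on the log2 scale at 120 than at 60 minutes, Ptchd4 2.02, the semaphorin Sema7a 1.96, and Cebpd, a transcription factor of adipocyte differentiation and inflammation, 1.88. Cdca7 (1.81), Myzap (1.71), Prag1 (1.71), Flrt3 (1.68), Angptl4 (1.68), an inhibitor of lipoprotein lipase, and Nrp1 (1.64), a receptor for semaphorins and VEGF, followed. Sema7a and Cdca7 had a 60 minute mean below the filter level, and offset 64 gave 1.29 and 1.1. Cebpd, Cdca7 and Angptl4 had fallen by 60 minutes, by log2 -0.22, -0.70 and -0.85, before lying above their starting level at 120 minutes by 1.66, 1.11 and 0.83.

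Run medians of the genotype difference ranged from log2 -0.21 to 0.21 over the 207 runs of 50 neighbouring genes. Their Spearman correlation between times was 0.789 for 0 and 60 minutes, 0.684 for 0 and 120 minutes and 0.744 for 60 and 120 minutes, across runs. The same sign at all 3 times was seen in 107 of 207 runs. Chance gives 25% only if no gene differs between genotypes. Gene order was not shuffled for these values, so lasting differences of single genes could give them without sharing among neighbours.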
